A study of Mus musculus with 22 samples.

How the data were processed

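RNA was sequenced from whole dorsal root ganglia (DRG) of mice and from cultured DRG neurons, 22 libraries in 8 groups. The 10 ganglion libraries came from wild-type (WT) mice and mice labelled Postn knock out (KO) after 5 days of vehicle or imiquimod (IMQ), and the 12 culture libraries from WT and KO neurons kept 72 h with or without recombinant POSTN (rPOSTN). Per the labels' protocols the libraries were poly-A selected, strand-specific by dUTP and sequenced in pairs of reads. The authors deposited 3 tables of raw read counts per Ensembl gene with no normalization: 1 table for the ganglia, 1 for the WT cultures and 1 for the KO cultures. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3, TopHat2 and the genome build GRCm39, with no role or order. The tool that counted reads, the strand setting, the annotation release and any filter are not given in the sources used here. The deposited counts were checked to be whole numbers, different in each library, and every column of the tables was matched to 1 sample by its label.

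Each table listed 55487 genes, of which 55141 were given a symbol from GENCODE M21. That annotation rests on another build than the one the submitters name, so genes are given by symbol and no coordinates are printed. Total counts per library ran from 16.7 to 24.1 M (mega) counts, and single-gene values are counts per M (CPM) on TMM-scaled library sizes, as mean ± SD of the group. Between replicates the chi-square of the counts per degree of freedom ran from 2.59 to 77.1, where 1 is counting error alone. A fold against a group with no count was computed against a floor of 3 counts over the group and is written as a lower bound. Counting limits cover counting error only, since reads without molecular identifiers are not independent molecules.

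Genes were tested with the edgeR 4.0.16 quasi-likelihood test (robust), two-sided, after filterByExpr and TMM, with Benjamini-Hochberg adjustment over all genes tested within a comparison. A gene was called at an adjusted p (FDR) below 0.05. If no gene changed, a share of 0.05 of the genes tested would have an unadjusted p under 0.05. Every count of such genes given below is smaller than that share, so none shows an excess of small p. Fold changes are log2 ± SE, where SE is the size of the fold change over the square root of its quasi-likelihood F statistic. The 4 ganglion groups shared 1 fit, because the IMQ groups held 2 libraries each. The WT and KO cultures were fitted apart, each from its own table, and a fit over all 12 culture libraries gave the difference of the rPOSTN effects. KO was not compared with WT in culture, because genotype and table coincide there. There were 8 comparisons: IMQ against vehicle in WT and in KO, the difference of these effects (interaction, KO minus WT), KO against WT in vehicle and in IMQ ganglia, rPOSTN against control in WT and in KO cultures, and the interaction of genotype and rPOSTN. R 4.3.3 and Python 3.11.15 were used.

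Of 39 gene lists written out by hand, covering neurons, glia, other cell types and pathways, each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members past the test were counted over all genes and adjusted over the list alone. Sets of genes called in 1 comparison were tested in another with camera and fry, which asks whether a set's genes move, on balance, one way. Where a comparison called fewer than 10 genes in a direction, the 100 genes with the smallest p in that direction were used.

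The comparisons, tests, lists and most alternatives were fixed before the data were examined, and so was the rule for named genes. That rule named Postn always. In each comparison it named the 10 called genes with the largest and the 10 with the smallest fold change whose libraries did not overlap between groups and whose mean was at least 1 CPM in either group, leaving out placeholder names. From each list with a called test or member it named up to 4 members with the smallest p. With fewer than 5 calls all were named, and with none the 5 genes with the smallest p. Not every gene that this rule names is reported here. Genes named outside this rule were chosen after their values were seen: those called under single alternatives, those given per library, Gpnmb, and Adgre1 for genotype in IMQ ganglia.

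Nothing in the labels says that replicates are separate animals or that replicate numbers pair the samples, so each p measures the spread between samples. Pairing was checked on the residuals of the libraries: with 3 pairs or more, numbers were taken to pair the samples where every pair correlated above 0.1 over genes with a mean log2 CPM above 3. These are correlations across genes within pairs of libraries, and genes are not independent replicates. The pairs correlated at 0.38, 0.37 and 0.68 in WT cultures, at 0.39, 0.71 and 0.63 in KO cultures, and at 0.87, 0.83 and 0.16 between WT and KO vehicle ganglia, where the last pair was not the best match. Residuals around a group mean are tied to each other. Where a single culture stands apart in both treatments, the others correlate whatever their numbers, so the bound alone cannot show pairing. In the cultures, each control library also correlated best with the rPOSTN library of its number. Pairing stays an assumption of the blocked fits. Blocked fits, with the replicate number as a term, are given beside those comparisons. Other ganglion contrasts had 2 pairs only and were not treated as paired.

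Alternatives were DESeq2 size factors in edgeR, no expression filter, DESeq2 1.42.0 itself, the replicate block, leaving out each library in turn, a fit over the 2 compared groups alone, a fit over all 12 cultures, and the estimated correlation. Alternatives added after seeing the data were a per-library gene-length offset (lowess span 0.3), that offset with the block, a block within genotype, and leaving out both treatments of culture 3. With a library left out, a lone remaining sample was assumed to vary like the other groups. The tests were checked on simulated counts with 200 changed genes per comparison at 1.5, 2 and 4-fold. At 2-fold the fraction recovered was 59.7% for IMQ in WT, 68.7% in KO, 16.4% for their interaction, 68.7% and 50.7% for genotype in vehicle and IMQ ganglia, 97% and 61.2% for rPOSTN in WT and KO cultures, and 62.7% for the culture interaction. Unchanged genes called in the simulated counts ran from 3 to 14 per comparison without the replicate block and from 4 to 26 with it. No library was left out of the reported comparisons.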

Results

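The series asked how periostin (POSTN, encoded by Postn), a secreted matricellular protein that binds integrins, acts on sensory ganglia in psoriasis. Gene expression was measured by RNA sequencing in DRG from WT and Postn KO mice treated for 5 days with vehicle or IMQ, a TLR7 agonist that causes psoriasis-like skin inflammation, and in DRG neuron cultures of both genotypes kept 72 h with or without rPOSTN. There were 3 WT vehicle ganglion libraries (17.3 to 20 M counts), 2 WT IMQ (16.8 to 19.6 M), 3 KO vehicle (17 to 22.3 M) and 2 KO IMQ (16.7 to 16.8 M). The cultures had 3 libraries in each of 4 groups: WT control (18.3 to 23.3 M), WT rPOSTN (18.3 to 24.1 M), KO control (18.3 to 19.2 M) and KO rPOSTN (18.5 to 19.1 M). Among the ganglia, WT IMQ 2 was the 1 library without Xist, the RNA of the inactive X chromosome (0.176 CPM, against 196 to 236 CPM in the others), and its 4 Y-linked genes summed to 141 CPM. WT cultures 1 and 2 had Y-linked counts and almost no Xist, WT culture 3 the reverse, and the KO cultures had both.

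Postn itself was measured first. In WT ganglia it stood at 22.9 ± 3 CPM with vehicle (n = 3) and 46.5 ± 4.55 CPM with IMQ (n = 2), a log2 difference of 1.02 ± 0.21 that missed the threshold (edgeR adjusted p = 0.0574, with 0.000996 to 0.41 over its alternatives). In KO ganglia Postn was at 4.11 ± 0.855 CPM with vehicle (n = 3) and 5.9 ± 2.15 CPM with IMQ (n = 2), which is 18% and 12.7% of the WT level. The WT cultures held far more Postn, 845 ± 136 CPM in controls and 880 ± 176 CPM with rPOSTN (n = 3 each). The KO cultures held 209 ± 173 CPM in controls and 204 ± 219 CPM with rPOSTN (n = 3 each), with culture 3 at 409 and 456 CPM and the other 4 libraries between 71.8 and 111 CPM. Counts of Postn reads do not show whether a functional transcript or protein was made.

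**Figure D1:**
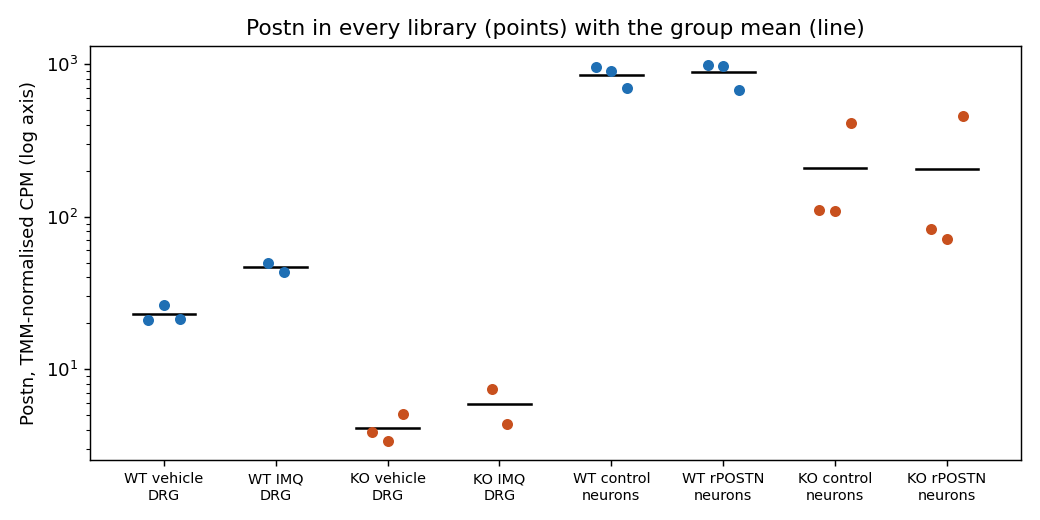
Postn in each library, in CPM on a log axis, by group, with points for libraries and bars for group means. KO ganglia lie at 3.39 to 7.43 CPM against 20.9 to 49.7 CPM in WT ganglia, and KO culture 3 stands apart from KO cultures 1 and 2.

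IMQ against vehicle in WT ganglia addressed what IMQ treatment of the mice does to the ganglion. This comparison does not separate skin inflammation from other effects of the drug. Macrophage genes rose. Adgre1, which encodes the macrophage surface protein F4/80, rose from 6.24 ± 0.737 to 63.3 ± 1.57 CPM (n = 3 and 2), by 3.34 ± 0.16 log2 (adjusted p = 2.56e-05). Itgam (CD11b) rose by 3.41 ± 0.26, the Fc receptor gene Fcgr4 by 4.25 ± 0.33, the lysosomal protease gene Ctss by 2.73 ± 0.18 and the complement gene C1qc by 2.13 ± 0.16. The acute phase gene Saa3 rose from 0.0744 ± 0.0648 to 9.69 ± 1.71 CPM, by 6.95 ± 0.45 (4 counts over the 3 vehicle and 353 over the 2 IMQ libraries). Fcrl5, an Fc receptor-like gene of B cells, and Cd300e, a myeloid receptor gene, rose from 1 and 2 counts over the 3 vehicle libraries to 167 and 141 counts over the 2 IMQ libraries. Cxcl13, a B cell chemokine gene with the largest fitted change (adjusted p = 0.0119), rose from 1 to 179 counts, and its adjusted p was 0.0681, 0.0744 and 0.0895 without WT vehicle 2, WT vehicle 3 and WT IMQ 1.

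In all, 224 of 17197 genes passed the test in WT ganglia, 193 higher and 31 lower. Mgl2, a lectin gene of alternatively activated macrophages and dendritic cells, fell by 3.87 on the log2 scale (SE 0.32), from 9.71 ± 0.907 to 0.668 ± 0.298 CPM. Drp2, a gene of the dystroglycan complex of myelinating Schwann cells, fell by 1.51 (SE 0.17), from 597 ± 77.9 to 210 ± 30 CPM. Of 34 called genes that the naming rule reached, 14 kept their call with any 1 library of the 2 groups left out, among them Adgre1, Itgam, Fcgr4, Ctss, C1qc, Saa3, Fcrl5, Cd300e, Mgl2 and Drp2, and 20 lost it without at least 1 library. Pdk4, a glucocorticoid- and fasting-induced regulator of glucose oxidation, fell by 1.29 (SE 0.16, adjusted p = 0.00396), and its adjusted p was 0.0651 without WT IMQ 1 and 0.0652 without WT IMQ 2. Bdnf, a neurotrophin gene of nociceptors, rose by 0.70 ± 0.12 (45.5 ± 5.91 to 74.1 ± 0.422 CPM, adjusted p = 0.0193), and its adjusted p was 0.0559, 0.0938, 0.161 and 0.173 without WT vehicle 1, WT vehicle 2, WT IMQ 1 and WT IMQ 2. DESeq2 called 358 genes, and edgeR called 120, 113, 107 and 82 without WT vehicle 2, WT vehicle 3, WT IMQ 1 and WT IMQ 2. Replicate numbers were not taken to pair these samples, and the blocked fit called 280 genes, 214 higher and 66 lower.

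By list, 14 of 22 measured macrophage genes rose in WT ganglia and none fell, and adjusted over the list alone 17 were higher and 1 lower (camera adjusted p = 3.99e-111). That list kept its call with an estimated correlation (adjusted p = 0.0012, with 2.27e-114 to 0.0012 over its alternatives). The 1 lower gene was Gpnmb, at −0.56 ± 0.19, a glycoprotein gene of lipid-laden macrophages. Of 42 interferon response genes, 6 rose, among them the antiviral genes Ifit1 (1.51 ± 0.17) and Oasl2 (1.10 ± 0.12), and 28 were higher adjusted over the list alone (camera adjusted p = 1.6e-33, and adjusted p = 0.0324 with an estimated correlation, the highest of its alternatives from 7.73e-35). Of 23 acute phase and STAT3 genes, 1 rose and 3 were higher adjusted over the list alone (adjusted p = 4.96e-07, and 0.0431 with an estimated correlation, range from 4.8e-07). Of 20 glucocorticoid response genes, 1 fell, Pdk4, and 8 were lower adjusted over the list alone, with a list median of −0.40 (adjusted p = 2.82e-09, and 0.0399 with an estimated correlation, range from 2.94e-10).

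Among 17 myelinating Schwann cell genes in WT ganglia, 1 fell, Drp2, and adjusted over the list alone 13 were lower and 1 higher, with a median of −0.85 (camera adjusted p = 4.85e-21). The myelin genes Mal (−0.95 ± 0.22) and Ugt8a (−0.81 ± 0.18) did not pass over all genes. The Schwann cell call was lost at adjusted p = 0.137 with an estimated correlation, and the median was −0.56 without WT IMQ 1. The same loss held for 9 other lists called by camera. The adipocyte list (9 genes, 1 higher, 7 adjusted over the list alone, median 1.57, but 0.64 without WT IMQ 2) stood at adjusted p = 0.167 with an estimated correlation. The cytokine, chemokine and NF-kB list (25 genes, 1 higher, 5 adjusted over the list alone, median 0.45, but 0.29 without WT IMQ 2) stood at 0.176, antigen presentation (19 genes, 0 called, 4 adjusted over the list alone, median 0.61) at 0.566 and erythroid genes (median −1.82) at 0.435. Of the 5 further lists, clock genes lost their call without WT IMQ 1 (0.203), proliferation genes without WT vehicle 1 (0.0636) or WT IMQ 1 (0.0786) and neutrophil genes without WT vehicle 1 (0.258) or WT IMQ 1 (0.203). Neuronal lists were not called in WT: itch receptors and pruriceptor markers had a median of 0.08 (camera adjusted p = 0.458), peptidergic nociceptor genes 0.04 (0.66), mechanoreceptor and proprioceptor genes 0 (0.859), excitability channels −0.04 (0.83), pan-neuronal genes 0.05 (0.474) and synaptic vesicle genes 0.05 (0.658). The nerve injury and regeneration list, with Bdnf as its 1 higher gene of 26, had a median of 0.03 (0.362).

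**Figure D2:**
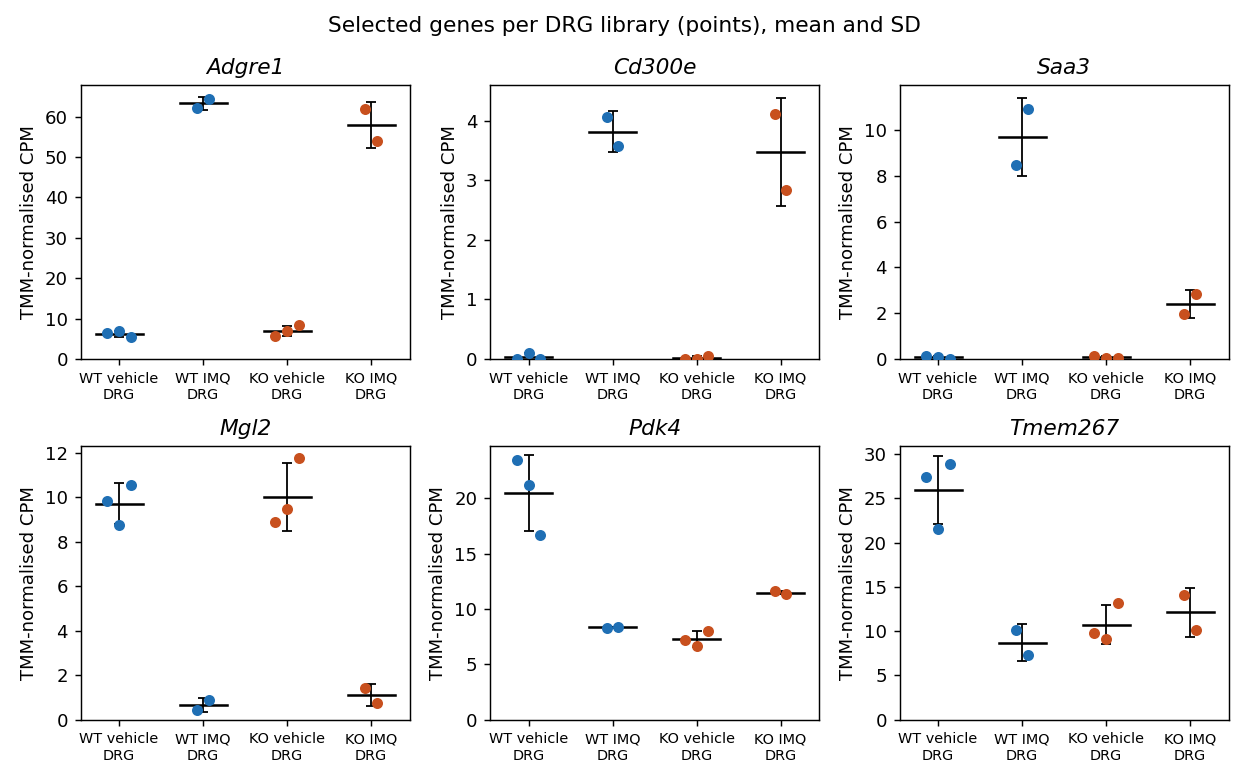
CPM in each ganglion library, by group, for genes named in the text, with points for libraries and bars for group means. Adgre1 lies at 62.2 and 64.4 CPM in the WT IMQ libraries and at 5.46 to 6.92 CPM in the WT vehicle libraries.

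IMQ against vehicle in KO ganglia asked for the same response without intact Postn. Macrophage genes rose here too. Adgre1 rose from 6.97 ± 1.28 to 57.9 ± 5.64 CPM (n = 3 and 2), by 3.05 ± 0.16 log2 (adjusted p = 3.72e-05), the C-type lectin receptor gene Clec4a3 by 3.19 ± 0.17, Fcgr4 by 3.99 ± 0.34, Ctss by 2.36 ± 0.18, C1qc by 1.86 ± 0.16 and the colony stimulating factor receptor gene Csf1r by 1.21 ± 0.11. Cd72, a B cell coreceptor gene, rose by 3.24 ± 0.32 and Saa3 by 4.98 ± 0.50, the latter from 4 counts over the 3 vehicle to 82 over the 2 IMQ libraries. Fcrl5 had no count in the 3 KO vehicle libraries and 114 in the 2 KO IMQ libraries, at least 65.1-fold higher. Mgl2 fell by 3.16 (SE 0.30), from 10 ± 1.52 to 1.11 ± 0.481 CPM.

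In KO ganglia 190 of 17197 genes passed, 187 higher and 3 lower: Mgl2, Retnla and Tcp11l1. Of 23 called genes that the naming rule reached, 14 kept their call with any 1 library of the 2 groups left out, among them Adgre1, Clec4a3, Fcgr4, Ctss, C1qc, Csf1r, Cd72, Saa3, Fcrl5, Ifit1, Oasl2, Ifi44 and Mgl2, and 9 lost it without at least 1 library. Retnla, which encodes a resistin-like protein of alternatively activated macrophages, fell by 2.81 (SE 0.43, adjusted p = 0.0126), with adjusted p of 0.0511, 0.118 and 0.142 without KO vehicle 3, KO IMQ 1 and KO IMQ 2. Tcp11l1 fell by 0.81 (SE 0.15, adjusted p = 0.0367), and its adjusted p was 0.0718, 0.0695, 0.106, 0.436 and 0.0585 without KO vehicle 1, 2, 3, KO IMQ 1 and 2. Of 42 interferon response genes 13 rose, among them Ifi44 (2.17 ± 0.27), Ifit1 (1.79 ± 0.17) and Oasl2 (1.22 ± 0.12), and 28 were higher adjusted over the list alone (camera adjusted p = 1.13e-46, and 0.013 with an estimated correlation, range from 1.13e-57). Of 22 macrophage genes 13 rose, and 17 were higher adjusted over the list alone (adjusted p = 1.4e-71, and 0.00624 with an estimated correlation, range from 1.43e-91). DESeq2 called 275 genes, edgeR over the 2 compared groups alone 58, and the blocked fit 239, 226 higher and 13 lower. Without KO vehicle 3, KO IMQ 1 and KO IMQ 2 the count was 110, 56 and 115.

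The other 15 lists called by camera in KO ganglia were lost with an estimated correlation. Cytosolic ribosomal protein genes (84 measured, 0 called, median −0.48) and oxidative phosphorylation genes (81, 0 called, median −0.46) stood at adjusted p = 0.768 with an estimated correlation, and their medians were −0.12 and −0.16 without KO vehicle 1 and −0.28 and −0.30 without KO IMQ 2. KO libraries differed in their trend of expression on gene length, with slopes from −0.221 in KO vehicle 1 to 0.158 log2 CPM per doubling in KO IMQ 2. Adipocyte genes (6 of 9 higher adjusted over the list alone, median 1.42) and cytokine, chemokine and NF-kB genes (1 of 25 higher, 10 higher and 1 lower adjusted over the list alone, median 0.61) stood at adjusted p = 0.239 with an estimated correlation. Fibroblast and matrix genes (6 of 24 higher adjusted over the list alone, median 0.36) and erythroid genes (6 of 9 lower adjusted over the list alone, median −2.43, but −0.97 without KO vehicle 1) stood at 0.634. Hbb-bs, a globin gene, was at 294 CPM in KO vehicle 1 and at 25 and 53.3 CPM in KO vehicle 2 and 3. The other 9 lists, myelinating Schwann cell genes among them (−0.29, 1 of 17 lower adjusted over the list alone, 0.768 with an estimated correlation), lost their call without at least 1 library as well. For Schwann cell genes these were KO vehicle 2 (0.0785), KO vehicle 3 (0.166), KO IMQ 1 (0.0634) and KO IMQ 2 (0.202). Neuronal lists were not called: itch receptors had a median of 0.03 (camera adjusted p = 0.388), peptidergic nociceptor genes 0.03 (0.638), mechanoreceptor genes 0 (0.589), excitability channels 0.09 (0.443), pan-neuronal genes −0.09 (0.169), synaptic vesicle genes 0.04 (0.965) and nerve injury genes −0.12 (0.443).

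The IMQ responses of the genotypes were set against each other directly. Of the genes called higher, 133 were shared by WT and KO, against 2.1 for independent lists, and all 193 WT genes were higher in KO as well. As a set these 193 genes had a median of 1.56 log2 in KO (limma fry p = 1.36e-05, camera p = 7.03e-05 with an estimated correlation). Of 31 genes called lower in WT, 25 were lower in KO, with a median of −0.21 (limma fry p = 0.0123, camera p = 0.0786 with an estimated correlation), and Mgl2 and Retnla were called in both, against 0.00541 for independent lists. In WT, Retnla fell by 2.11 (SE 0.40, adjusted p = 0.0377), and its adjusted p was 0.0933, 0.102, 0.0923, 0.0749 and 0.342 without WT vehicle 1, 2, 3, WT IMQ 1 and 2. In both genotypes the IMQ groups had 2 libraries each.

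**Figure D3:**
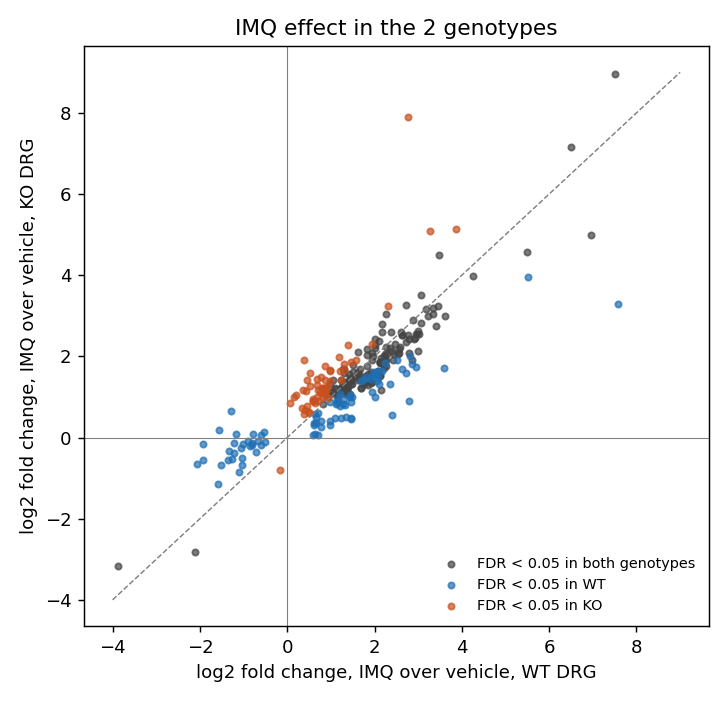
Log2 fold change with IMQ in WT ganglia (x axis) against KO ganglia (y axis) for genes called in either genotype, with the diagonal of equal change. All 193 genes called higher in WT also lie above 0 on the KO axis, and 133 of them were called there.

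For the difference between these responses, no gene passed: edgeR called 0 of 17197, with 364 at an unadjusted p under 0.05, and DESeq2 called 5. Those 364 are fewer than the share of 0.05 that no change at all would give. The smallest adjusted p was 0.155, for Pdk4, whose interaction was 1.95 ± 0.23 (0.0302 with the length offset, added after seeing the data, with 2.49e-07 to 1 over its alternatives). Pdk4 fell with IMQ in WT, from 20.5 ± 3.42 to 8.36 ± 0.0342 CPM, and stood at 7.29 ± 0.714 and 11.5 ± 0.168 CPM in KO vehicle and KO IMQ. DESeq2 called Pdk4 (1.94), Slc15a2, a peptide transporter gene (−2.77), the X-linked gene Xlr3b (−2.45), Tmem267 (1.75) and Gm1821. Without WT IMQ 1 the 1 call was Xist, which follows the sex of the remaining WT IMQ library.

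Of 20 glucocorticoid response genes, 0 passed for the interaction and 2 were higher adjusted over the list alone, with a median of 0.46 (camera adjusted p = 5.6e-16). That list kept its call with an estimated correlation (adjusted p = 0.0247, with 2.54e-22 to 0.0247 over its alternatives). Besides Pdk4, its members Hif3a (1.12 ± 0.37) and Mertk (0.87 ± 0.24) did not pass. The myelinating Schwann cell list had a median of 0.54, with Drp2 at 0.84 ± 0.22 (adjusted p = 7.28e-15, and adjusted p = 0.339 with an estimated correlation), and the median was 0.33 without WT IMQ 1 and 0.84 without WT IMQ 2. The macrophage list had a median of −0.33 (0.00109, and adjusted p = 0.714 with an estimated correlation), and the interferon list 0.18 (0.00247, and adjusted p = 0.714 with an estimated correlation). The macrophage list stood at adjusted p = 0.05 without KO IMQ 2, and the interferon call was lost without WT vehicle 1 (0.0731), WT IMQ 1 (median 0.08, 0.129), KO vehicle 2 (0.10, 0.463) or KO IMQ 1 (0.106). For interactions the simulated data gave recovery of 16.4% at 2-fold and 83.3% at 4-fold, so a 2-fold difference was rarely recovered with 2 and 3 libraries.

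**Figure D4:**
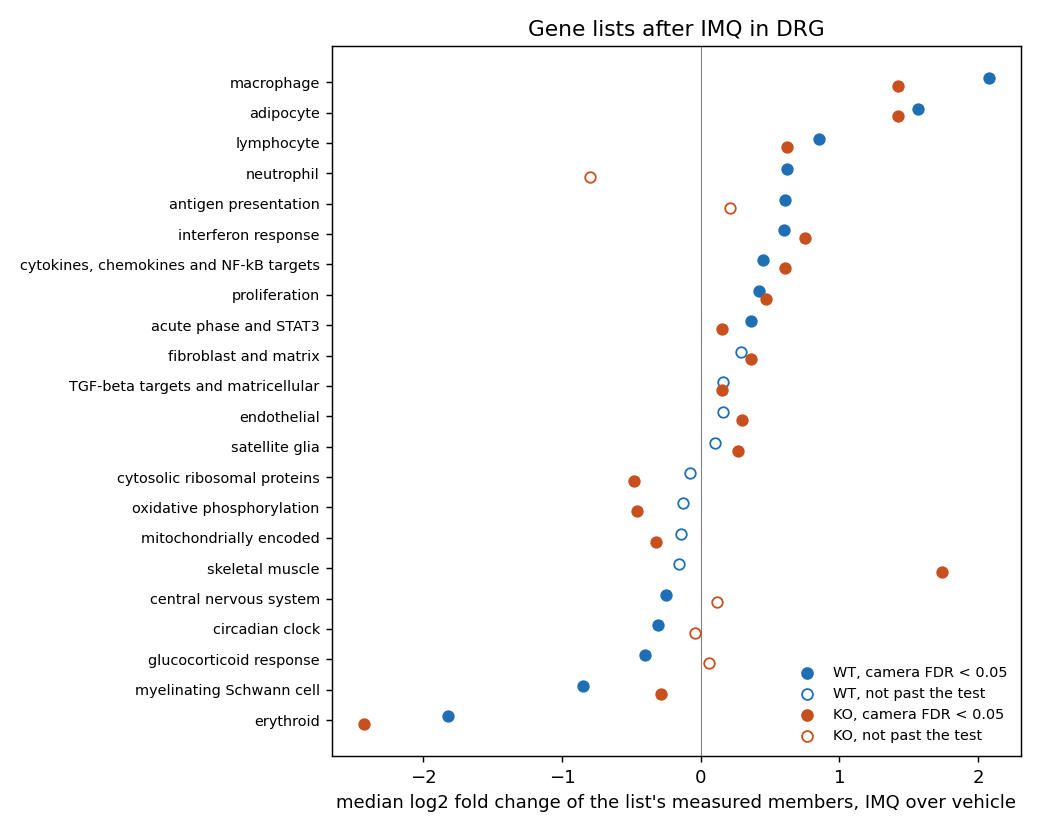
Median log2 fold change with IMQ of each gene list called in at least 1 genotype, in WT and KO ganglia. The macrophage list stands at 2.08 in WT and 1.42 in KO, and the interferon list at 0.60 and 0.75.

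KO against WT in vehicle ganglia asked what the loss of Postn does without inflammation. Postn was lower by a log2 of −2.48 ± 0.22 (adjusted p = 0.011; n = 3 and 3) and Pdk4 by −1.49 ± 0.14 (7.29 ± 0.714 against 20.5 ± 3.42 CPM, adjusted p = 0.0147), and no other gene passed. The replicate block kept both (Postn at 0.00943, Pdk4 at 0.0135) and added Tmem267, at −1.28 ± 0.12 (adjusted p = 0.00979, against 0.221 unblocked). Of 24 fibroblast and matrix genes 0 passed and 11 were lower adjusted over the list alone, with a median of −0.50 (camera adjusted p = 2.67e-29, lost at adjusted p = 0.0592 with an estimated correlation), among them Col3a1 (−0.87 ± 0.17), Lox, a collagen crosslinking enzyme gene (−1.33 ± 0.22), and Fbn1 (−0.91 ± 0.20).

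At 530 genes with an unadjusted p under 0.05, edgeR called 2 of 17197 and DESeq2 30 in this comparison. Of 20 glucocorticoid response genes, 1 fell, Pdk4, and 4 were lower adjusted over the list alone, with a median of −0.37 (camera adjusted p = 1.87e-32). That list kept its call with an estimated correlation (adjusted p = 0.00385, with 1.15e-34 to 0.00385 over its alternatives). Of 17 myelinating Schwann cell genes 0 passed and 13 were lower adjusted over the list alone, with a median of −0.66, or −0.42 without WT vehicle 1 (adjusted p = 6.6e-35, and adjusted p = 0.0592 with an estimated correlation). Skeletal muscle genes had a median of −2.40, or −3.63 without KO vehicle 2 (3.88e-16, and adjusted p = 0.245 with an estimated correlation), with the muscle actin gene Acta1 at 24.3, 1.21 and 24.2 CPM in the WT and 1.7, 6.74 and 1.11 CPM in the KO libraries. Heat shock genes (median 0.23) and pan-neuronal genes (0.11) were called by camera and lost at adjusted p = 0.0592 and 0.201 with an estimated correlation. So were 11 other lists, of which 9 lost their call without at least 1 library as well. Without WT vehicle 2, KO vehicle 1, KO vehicle 2 or KO vehicle 3 the number of calls was 0, with Postn at adjusted p of 0.0667, 0.063, 0.0612 and 0.0571 and Pdk4 at 0.125, 0.0866, 0.0953 and 0.103, and edgeR over the 2 groups alone called 1.

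KO against WT in IMQ ganglia asked what the loss of Postn does in the inflamed state. Postn was the 1 gene that passed, lower by a log2 of −2.98 ± 0.26 (5.9 ± 2.15 against 46.5 ± 4.55 CPM, n = 2 and 2, adjusted p = 0.0118). Adgre1, at 57.9 ± 5.64 CPM in KO and 63.3 ± 1.57 CPM in WT, did not pass. Saa3, at 2.41 ± 0.614 CPM in KO and 9.69 ± 1.71 CPM in WT, differed by −2.01 ± 0.33 and did not pass (adjusted p = 0.997), while DESeq2 gave 0.00449 and the 2 groups alone 0.00758 (0.00449 to 1 over its alternatives). Col3a1 stood at −0.77 ± 0.21 and Bdnf at −0.51 ± 0.13, both short of the threshold. In all, 318 genes had an unadjusted p under 0.05, and DESeq2 called 4: Postn, Saa3 and the Y-linked Uty and Eif2s3y.

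All 17 lists called by camera in IMQ ganglia were lost with an estimated correlation. Fibroblast and matrix genes had a median of −0.33 (0 of 24 passed, camera adjusted p = 1.94e-08, adjusted p = 0.372 with an estimated correlation), interferon response genes 0.24 (0 of 42 passed, 8.23e-08, adjusted p = 0.329 with an estimated correlation), and nerve injury genes −0.17 (3.03e-05, adjusted p = 0.329 with an estimated correlation). The fibroblast median was −0.53 without WT IMQ 1 and −0.09 without WT IMQ 2, where the call was lost (0.081). Macrophage genes had a median of −0.21 (0.00138, adjusted p = 0.659 with an estimated correlation), lost without WT IMQ 1 (0.0607) or KO IMQ 2 (median −0.10, 0.229) and at −0.33 without KO IMQ 1. Of the 17 lists, 13 lost their call without at least 1 library. Postn was the gene lost without WT IMQ 2 (adjusted p = 0.0976) or KO IMQ 2 (0.127), where the count was 0, and without WT IMQ 1 (0.0874), where the 1 call was Xist. The fit over the 2 groups alone called 5 genes, Postn, Saa3, the myosin genes Myh1 and Myh2 and Gm1821.

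rPOSTN against control in WT cultures asked how neurons respond to the protein. No gene passed in the unblocked test: edgeR called 0 of 16639 (n = 3 and 3), with 661 at an unadjusted p under 0.05, and DESeq2 called 0. The genes with the smallest p were Plxna4, a semaphorin coreceptor gene (0.16 ± 0.04), Cyp1a1, a target of the aryl hydrocarbon receptor (−0.31 ± 0.08), the ribosomal gene Rpl26 (−0.22 ± 0.06), the spindle gene Spdl1 (0.59 ± 0.16) and Gm19557 (1.81 ± 0.47), each at an adjusted p of 0.999. Postn mRNA differed by 0.06 ± 0.22. In simulated data of this size 85.1% of 1.5-fold changes were recovered.

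With culture number as a block, 8 genes passed in WT, 7 higher and 1 lower, all at 0.999 unblocked. Mir6236 and Gm15564, annotated transcripts that overlap ribosomal RNA sequence, were higher by 1.06 ± 0.10 (adjusted p = 7.27e-07) and 0.92 ± 0.17 (0.0242), and ENSMUSG00000118642 by 0.80 ± 0.09 (2.33e-05). The long non-coding RNAs Meg3 and Miat were higher by 0.20 ± 0.03 (0.00159) and 0.18 ± 0.03 (0.0351), Gm24270 by 0.94 ± 0.06 (0.00196) and 9930022D16Rik by 0.89 ± 0.17 (0.0302). Actb, the cytoskeletal actin gene, was lower, at −0.16 ± 0.03 (0.0242). The cytosolic ribosomal protein list had a median of −0.15 (0 of 82 passed, 13 lower adjusted over the list alone, camera adjusted p = 7.51e-27, and adjusted p = 0.886 with an estimated correlation). Oxidative phosphorylation genes (−0.09, or −0.05 without WT rPOSTN 2 and −0.16 without WT rPOSTN 3) stood at adjusted p = 0.886 with an estimated correlation, and excitability channels (0.07) at 0.546. All 6 lists that camera called unblocked here were lost with an estimated correlation, and 4 of them kept their call without each library in turn. Interferon response genes lost their call also without WT control 1 (0.697), WT control 2 (0.49) or WT rPOSTN 3 (0.49), and fibroblast genes without WT control 2 (0.147), WT control 3 (0.258), WT rPOSTN 1 (0.314) or WT rPOSTN 2 (0.823). With the block, camera also called pan-neuronal genes (median 0.04, adjusted p = 0.0114), antigen presentation genes (−0.07, 0.027) and the integrated stress list (−0.05, 0.0223), which stood unblocked at adjusted p = 0.886 with an estimated correlation. The blocked test was not run with an estimated correlation. Itch receptors (0.03, camera adjusted p = 0.331) and peptidergic nociceptor genes (0.02, 0.979) were not called. With both treatments of culture 3 left out, an alternative chosen after seeing the data, 334 genes passed, 61 higher and 273 lower, of which 106 (31.7%) had the same sign in culture 3. The same setting called 0 genes in KO cultures and 0 for the interaction of genotype and rPOSTN, so a difference between genotypes was not shown. Recovery was not simulated for that setting. The counts of WT cultures 1 and 2 lay close together. Their chi-square per degree of freedom was 2.59 in controls and 2.93 with rPOSTN, against 8.3 to 17.1 with culture 3. The 334 calls thus rest on a small spread, which may not be that between animals.

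rPOSTN against control in KO cultures asked the same where Postn was disrupted. edgeR called 0 of 16756 genes (n = 3 and 3), with 155 at an unadjusted p under 0.05, DESeq2 called 0, and the blocked fit called 0, with a smallest adjusted p of 0.251. Among the genes with the smallest p was Fam221b (−1.86 ± 0.53), at an adjusted p of 1. The glycolysis and hypoxia list had a median of 0.39, with Eno1 at 0.41 ± 0.33 and Pgam1 at 0.38 ± 0.29 (0 of 22 passed and 0 adjusted over the list alone, camera adjusted p = 0.000743, and adjusted p = 0.957 with an estimated correlation). Acute phase and STAT3 genes (median 0.06, C3 at 2.04 ± 0.72, camera adjusted p = 0.0445, and adjusted p = 0.8 with an estimated correlation) and cytokine, chemokine and NF-kB genes (0.20, camera adjusted p = 0.0445, and adjusted p = 0.957 with an estimated correlation) had 0 members past the test. The glycolysis call was lost without KO control 3 (0.101) or KO rPOSTN 2 (0.14), where its median turned to −0.15, and the median was 0.66 and 0.65 without KO control 2 and KO rPOSTN 3. The acute phase call was lost without KO rPOSTN 3 (0.437), with medians of 0.03, 0.16, 0.19 and 0.14 without KO control 2, KO control 3, KO rPOSTN 1 and KO rPOSTN 2. The cytokine median was 0.33 without KO control 3 and 0.44 without KO rPOSTN 1, and the call was lost without KO control 1 (0.225), KO control 2 (0.202), KO rPOSTN 2 (median 0.05, 0.771) or KO rPOSTN 3 (0.141). With the block the nerve injury list was called as well (median 0.03, adjusted p = 0.0381), which stood unblocked at adjusted p = 0.8 with an estimated correlation.

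The difference of the rPOSTN effects between genotypes had no gene past the test. edgeR called 0 of 17519, with 342 at an unadjusted p under 0.05, and DESeq2 called 0. The blocked fit also called 0, but it gave WT and KO cultures of the same number a shared term. Nothing pairs cultures across genotypes, so that 0 is not the result for the pairs within each genotype. A block within genotype, added after seeing the data, called Gm23935 and Gm24270, both lower in the KO minus WT difference (−1.13 and −1.01). The ribosomal list had a median of 0.13 (camera adjusted p = 1.29e-07, and adjusted p = 0.983 with an estimated correlation), glycolysis and hypoxia genes 0.42 (0.0159, and adjusted p = 0.983 with an estimated correlation; −0.14 without KO rPOSTN 2) and acute phase genes 0.10 (0.0337, and adjusted p = 0.93 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. The ribosomal call was lost without KO rPOSTN 1 (median 0.06, 0.1), the glycolysis call without KO control 1 (0.152), KO control 3 (0.274) or KO rPOSTN 2 (0.166), and the acute phase call without WT control 1 (0.0534), WT control 2 (0.117), WT rPOSTN 3 (0.235), KO control 1 (0.152), KO control 2 (0.126) or KO rPOSTN 3 (0.285). Medians also moved without KO rPOSTN 3 (ribosomal 0.20, glycolysis 0.67) and KO control 2 (glycolysis 0.68), and for acute phase genes without WT control 1 (0.06), WT control 3 (0.16), KO control 1 (0.05), KO control 3 (0.22) and KO rPOSTN 1 (0.16).

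The IMQ genes of the ganglion were then followed in the cultures. Immune cell genes are among them, such as Adgre1, which stood at 2.38 to 7.81 CPM in the cultures. A rise through more immune cells in a ganglion could not appear in a culture, so these tests say little of such genes. Of the 193 genes called higher with IMQ in WT ganglia, 154 were measured in WT cultures and 79 of these were higher with rPOSTN, with a median of 0.01 (limma fry p = 0.91, camera p = 0.826 with an estimated correlation), and of 136 measured in KO cultures 74 were higher, with a median of 0.03 (limma fry p = 0.94, camera p = 0.834). The 22 and 23 measured of the 31 lower genes gave limma fry p = 0.651 and 0.611, and camera p = 0.695 and 0.449 with an estimated correlation. The 100 genes with the smallest p in each direction for rPOSTN in WT cultures were not called as sets in KO cultures (limma fry p = 0.656 and 0.957, camera p = 0.628 and 0.998 with an estimated correlation). None of those genes had passed in WT (smallest edgeR adjusted p 0.999), so the sets may hold no response. Their test thus cannot decide whether a response is shared.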

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

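Chosen only after the result was seen were the length-trend and shared-response tests of the blocked WT culture genes, the 3 tests of Postn in KO cultures, the 3 tests of Pdk4 in WT vehicle ganglia, and the count of splits for genes called between genotypes in vehicle ganglia. The results here are lists whose IMQ effect, or rPOSTN effect, differed between WT and KO by a test of the difference itself (camera at a preset correlation). For IMQ the differences, KO minus WT as list medians, were 0.46 for glucocorticoid response, 0.54 for myelinating Schwann cell, −0.40 for cytosolic ribosomal protein, −0.35 for oxidative phosphorylation, −0.42 for antigen presentation and −1.34 for neutrophil genes. They were 0.37 for central nervous system, −0.33 for macrophage, 0.35 for circadian clock, 0.18 for interferon response, 1.98 for skeletal muscle and −0.19 for pan-neuronal genes. They were 0.13 for fibroblast and matrix, 0.19 for immediate early, −0.18 for nerve injury and 0.05 for satellite glia genes. For rPOSTN they were 0.13 for cytosolic ribosomal protein, 0.42 for glycolysis and hypoxia and 0.10 for acute phase and STAT3 genes. Leaving out 1 library turned the median of 6 of these lists: skeletal muscle to −0.52 and satellite glia to −0.05 without KO IMQ 1, satellite glia to −0.06 without WT IMQ 1, neutrophil to 0.01 without KO vehicle 1, immediate early to −0.04 without KO IMQ 2, nerve injury to 0.07 without WT IMQ 2, and glycolysis to −0.14 without KO rPOSTN 2. Leaving out a single library moved the medians of 9 of the other 13 by more than 1.5 times as well. Without KO vehicle 1 the ribosomal protein and oxidative phosphorylation differences for IMQ were −0.06 and −0.05 and lost their calls. Of the 16 lists for IMQ 4 kept their call without each library in turn, and of the 3 for rPOSTN 0 did. With an estimated correlation, glucocorticoid response was the 1 list of these 19 past the threshold (adjusted p = 0.0247, with 2.54e-22 to 0.0247 over its alternatives).

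Pdk4 and the glucocorticoid response list were higher in WT vehicle ganglia than in the 3 other ganglion groups. Skeletal muscle carried over in dissection is argued against by the libraries within groups, where Pdk4 changed by −0.03 ± 0.05 and the glucocorticoid list by 0 ± 0.03 log2 per log2 of the muscle list, against the 0.82 and 0.31 that the difference between WT and KO vehicle needs. For a different time of day of collection, the mean contrast of clock genes in KO vehicle lay 0.13 from WT vehicle (SD within groups 0.16), which argues against a large shift. Single clock genes did differ: Arntl was at 4.5, 4.4 and 6.71 CPM in WT vehicle against 2.25, 2.35 and 2.16 in KO vehicle. So time of day is not settled for KO vehicle. WT IMQ lay at −0.91 and KO IMQ at −0.29, so it stays open for these groups. The trend on gene length is argued against as the whole cause for Pdk4, which kept an adjusted p of 0.00564 between genotypes with that trend removed (5.09e-13 to 0.198 over its alternatives), and was not tested for the list. Handling, feeding or stress of the animals, and a loss of Postn acting on glucocorticoid targets, stay open and were not tested.

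Postn transcript remained in the KO cultures, most in culture 3. Its control library had 48.4% of the WT control mean, and wild-type cells among the cultured cells cannot be told apart from a transcript left by the disrupted gene, because no table holds the allele. For fibroblast content, Postn per fibroblast list was 2.33 and 2.9 times that of KO cultures 1 and 2 (control, rPOSTN). The list itself was higher too (93.6 and 107 CPM against 51.5 to 61.2). The collagen gene Col1a1 differed more than the list, at 130.7 and 167.5 CPM against 38.1 to 63.8. The ratio thus depends on the genes taken for fibroblasts, and fibroblast content stays open. The 4 Y-linked genes also differed, at 103 CPM in both culture 3 libraries against 47.4 to 50.6, so another make-up of that culture stays open. A library exchanged with the WT table is argued against by 7 of 7 mitochondrially encoded genes, at which both culture 3 libraries lay below every WT library, although over 83 separating genes 48.2% and 42.2% were nearer to KO, short of the bound of 90% first written for that test.

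With WT cultures taken as paired, 7 genes were called higher after rPOSTN, among them transcripts that overlap ribosomal RNA and the long non-coding RNAs Meg3 and Miat. Some of these transcripts also varied widely between libraries of the same group. In KO IMQ ganglia 1 and 2, Mir6236 was at 25.9 and 1.6 CPM and Gm24270 at 19 and 1.54 CPM. The cause of that variation was not tested, and it limits what their change in cultures can show. The gene-length trend is argued against as the whole cause, since 7 of 8 blocked calls stayed with it removed. The lost call was Gm24270, whose fold change was 1.06 with the trend removed and 0.94 before (blocked edgeR adjusted p = 0.789). The trend was fitted on protein-coding genes. ENSMUSG00000118642, without a symbol from the annotation, stood at 0.80 before and after, so the test says little for it. A response shared by both genotypes is argued against by the KO cultures, where the 8 genes had a median of −0.06 in the WT direction and 2 of 8 moved that way, Mir6236 (0.48 ± 0.28) and Gm15564 (0.36 ± 0.37), so for these 2 it stays open. More nuclear RNA in the rPOSTN libraries stays open. In the blocked fit, with the length trend not removed, 7 other nuclear long non-coding RNAs had a median of 0.13 and 6 of them were higher. None passed that test (smallest adjusted p 0.0804, for Rian), and Neat1 stood at −0.02 ± 0.05. Malat1 was 1124 and 1126, 1543 and 1310, and 1128 and 3672 CPM in the 3 pairs (control, rPOSTN). Of 4 swaps within pairs 2 gave as many calls (8 for the real one, 184 for the highest other), too few swaps for a share under 0.05, and the 184, with culture 3 swapped, point to a structure of the samples or to an opposite effect in culture 3, which these swaps do not separate.

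The 6 samples of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. Between genotypes in vehicle ganglia 2 of 10 gave as many genes (2, highest other 5184) and 2 of 10 as many lists (17, highest other 20). The split with 5184 genes set WT vehicle 1, KO vehicle 1 and KO vehicle 3, whose length slopes were −0.175, −0.221 and −0.039, against libraries at 0.084, 0.067 and 0.139, which points to a structure of the samples along gene length. For rPOSTN in WT cultures 10 of 10 gave as many genes (0 by edgeR, highest other 4, with 661 at an unadjusted p under 0.05 and 0 by DESeq2) and 5 of 10 as many lists (6, highest other 17). In KO cultures 10 of 10 gave as many genes (0 by edgeR, highest other 0, with 155 at an unadjusted p under 0.05 and 0 by DESeq2) and 10 of 10 as many lists (3, highest other 18). For the interaction in cultures, of 80 splits drawn at random, 80 gave as many genes (0 by edgeR, highest other 14, with 342 at an unadjusted p under 0.05 and 0 by DESeq2) and 75 as many lists (3, highest other 17), so chance is not excluded for its lists in the unpaired test. The splits in this paragraph were made without regard to the pairs of cultures or of vehicle ganglia, so they say nothing of a paired contrast. With WT cultures 1 and 2 alone, 1 of 3 splits, the real one, gave as many genes (334, highest other 1), too few for a share under 0.05.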

How the results depend on the processing

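The gene-length offset, alone or with the replicate block, the block within genotype and leaving out both treatments of culture 3 were alternatives added after seeing the data. DESeq2 called 358 genes for IMQ in WT, 5 for the IMQ interaction, and 30 and 4 between genotypes in vehicle and IMQ ganglia. No expression filter gave 2 for the IMQ interaction, 22 and 2 between genotypes, and 2 for rPOSTN in WT. The length offset gave 1 and 4 for the IMQ interaction and genotype in vehicle, and with the block 425, 385, 2 and 21 for IMQ in WT, IMQ in KO, the interaction and genotype in vehicle, and 12 for rPOSTN in WT. The replicate block gave 8 for rPOSTN in WT, the block within genotype 2 for the rPOSTN interaction, and leaving out culture 3 gave 334 in WT. The 2 compared groups alone gave 58 for IMQ in KO, and 1 and 5 between genotypes in vehicle and IMQ ganglia. With an estimated correlation the lists called numbered 4 and 2 for IMQ in WT and KO, 1 for their interaction, 1 and 0 between genotypes, and 0 in each culture comparison. In these cases the cause was not tested. With 1 library left out, a lone sample being assumed to vary like the other groups, counts ran from 82 to 160 for IMQ in WT (120, 113, 107 and 82 without WT vehicle 2, WT vehicle 3, WT IMQ 1 and WT IMQ 2) and from 56 to 165 in KO (110, 56 and 115 without KO vehicle 3, KO IMQ 1 and KO IMQ 2). They ran from 0 to 1 for the interaction (1 without WT IMQ 1), 0 to 2 for genotype in vehicle (0 without WT vehicle 2 or KO vehicle 1, 2 or 3) and 0 to 1 for genotype in IMQ ganglia (0 without WT IMQ 2 or KO IMQ 2). Lists ran from 5 to 11 for rPOSTN in WT (11 without WT control 3), 3 to 10 in KO (6, 10, 10 and 8 without KO control 3 and KO rPOSTN 1, 2 and 3) and 2 to 11 for their interaction (6, 5, 5, 11 and 6 without WT control 3, KO control 3 and KO rPOSTN 1, 2 and 3). Some list medians reversed with 1 library left out, as ranges over the libraries: for IMQ in KO, acute phase −0.01 to 0.32 (low without KO vehicle 2) and skeletal muscle −0.91 to 2.6 (KO IMQ 1); for the IMQ interaction, neutrophil −2.1 to 0.01 (high without KO vehicle 1), muscle −0.52 to 2.88 (low without KO IMQ 1), immediate early −0.04 to 0.48 (KO IMQ 2), nerve injury −0.32 to 0.07 (high without WT IMQ 2) and satellite glia −0.06 to 0.27 (low without WT IMQ 1, −0.05 without KO IMQ 1). Between genotypes in vehicle ganglia they were oxidative phosphorylation −0.14 to 0.44 (low without KO vehicle 1), synaptic vesicle −0.01 to 0.16 (WT vehicle 1) and ribosomal protein −0.23 to 0.48 (low without KO vehicle 1, −0.01 and −0.03 without WT vehicle 2 and 3). In IMQ ganglia they were muscle −3.07 to 0.48 (high without KO IMQ 2), cholesterol synthesis −0.22 to 0.03 (KO IMQ 1), excitability −0.03 to 0.27 (low without KO IMQ 2), TGF-beta targets −0.35 to 0.10 (high without WT IMQ 2) and mitochondrially encoded −0.70 to 0.02 (KO IMQ 2). In cultures they were interferon in WT −0.13 to 0.01 (high without WT rPOSTN 3), and glycolysis in KO −0.15 to 0.66 and for the interaction −0.14 to 0.68 (both low without KO rPOSTN 2). Past the threshold in the new direction was the ribosomal protein list in vehicle ganglia without KO vehicle 1 (−0.23). Beyond these, list values kept direction and call in 633 cases and direction alone in 200, while named genes stayed on their side of the threshold in 5372, lost it in 134 and gained it in 173. At these depths few-count genes such as Fcrl5 in vehicle ganglia (1 count in WT, 0 in KO) have folds limited by counting.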

Other observations

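The setting with WT cultures 1 and 2 alone was chosen only after the result was seen, and so was every value in this part. In those cultures 70 of 82 cytosolic ribosomal protein genes and 31 of 81 oxidative phosphorylation genes were called lower with rPOSTN. These calls rest on the small spread between cultures 1 and 2. Over the same pairs the slope of expression on gene length went from −0.002 to 0.040 and from 0.006 to 0.046 log2 CPM per doubling, and in culture 3 from 0.021 to 0.026. Rpl35a stood at −0.49 there and at 0.22 in culture 3, and Col1a1 at 0.30 and −0.23, while Mir6236 stood at 1.02 and 1.1. Cultures 1 and 2 had Y-linked counts and culture 3 had Xist, so sex and culture number coincide.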
